A study of Arabidopsis thaliana with 12 samples.

How the data were processed

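Transcripts were measured in whole 14-day-old Arabidopsis thaliana seedlings of a Col-0 line that carries ribosomal protein L18B with a His6-FLAG tag, driven by the near-constitutive 35S promoter. The tag lets ribosomes, with the mRNAs they carry, be captured on anti-FLAG beads. RNA from this capture is called polysomal RNA here, and RNA taken from the same clarified extract before capture is called total RNA. Seedlings were sampled after 1 h of continued light, after 1 h of darkness begun in the middle of the light period, or after that darkness and 10 min of light. Each of the 3 conditions has 2 arrays of total and 2 of polysomal RNA, which makes 6 groups and 12 Affymetrix ATH1 arrays. Per the labels, the 2 arrays of a group come from independent biological replicate experiments.

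Per the submitters' processing notes, the authors used RMA and affy, whose versions are not stated there, and the deposited values are log2 expression per probe set. RMA corrects background, makes the distributions of the arrays it is given alike by quantile normalization, and summarizes the probes of a set. Every change is therefore relative to the rest of the array, and a loss or gain of all transcripts together would not show. The values had array medians between log2 6.04 and 6.19. No genome build is given in the sources used here, so no coordinates are printed. Arrays have no counting depth, and the number of arrays limits the precision: the median standard error of a difference between groups was 0.13 on the log2 scale, and 0.19 for a change of the polysomal-to-total ratio.

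The table holds 22810 probe sets. After 64 control probe sets were set aside, 22746 were tested. The platform annotation pairs 13513 of these (59.4%) with 1 gene, 503 with several genes, and does not list 8730. Genes are named only from probe sets with 1 gene, through a reference gene table of assembly TAIR10.1, which matched 13436 of them and did not match 77. In all, 13356 genes had a probe set of their own, and a gene was represented by the probe set least open to cross-hybridization by its name, then by the highest mean. RPL18B, ASN1, HY5 and LHCB1.1 were to be named in any case but had no probe set tied to them alone, so they are not analysed here.

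A linear model with 6 group means was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation, so that the groups share 1 estimate of the spread (6 residual and 5.48 prior degrees of freedom). Tests were two-sided and adjusted by Benjamini-Hochberg over the 22746 probe sets, and a probe set was called at an adjusted p under 0.05. The comparisons were darkness over light, reillumination over darkness and reillumination over light in each RNA pool, polysomal over total RNA in each condition, and the change of that ratio between conditions (an interaction). Counts of shared calls are set beside the count of independent lists and beside 20 simulations of unchanged groups that use the same arrays. Few probe sets can be called where no group changes. The simulated counts therefore cannot show how many shared calls the shared arrays make among changed probe sets. Errors after ± are standard errors of the fit with n = 2 arrays per group, unless an SD is named. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

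The design, the rule for named genes, the main alternatives and the lists of light harvesting and photosystems, Calvin cycle, dark and sugar-starvation induced, PIF and shade-response, HY5-type light-induced, circadian clock, rapid stress-response, heat shock, auxin-response, root marker, translation factor, conserved upstream open reading frame (uORF), starch breakdown and nitrogen assimilation genes, with the organelle-encoded transcripts, core histones and ribosomal proteins by a rule on names, were fixed before the data were examined. The annotation holds no gene descriptions, so the rule on names found 0 ribosomal proteins, and the organelle-encoded transcripts were matched by chromosome in the reference table. Many fixed members lacked a probe set of their own, among them all 8 heat shock and all 6 nitrogen assimilation genes. Further lists were therefore written from the gene names in the annotation, or from known loci, before any fit was run: cytosolic and plastid ribosomal proteins by locus, ribosome biogenesis, autophagy, branched-chain amino acid breakdown, chlorophyll and tetrapyrrole synthesis, nuclear-encoded thylakoid complexes, expansins and xyloglucan enzymes, tubulins, sugar transporters, glutathione S-transferases, elicitor and calcium response, tricarboxylic acid cycle and respiration, and UDP-glucosyltransferases. The 21 lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01, adjusted over the 21 lists within a comparison, and again with the correlation estimated from the data. Of 252 such tests 65 were called, and 10 were with an estimated correlation. Those 10 are the chloroplast-encoded and the mitochondrion-encoded transcripts in polysomal over total RNA in all 3 conditions, the chloroplast-encoded transcripts in polysomal RNA in darkness over light and in reillumination over darkness, and the dark and sugar-starvation and branched-chain lists in polysomal RNA in darkness over light. The median, the mean and the test differed in sign for 0 of the 65 and for 34 of the lists that were not called.

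For each comparison the named genes are the 6 largest rises and 6 largest falls among called genes whose arrays separate without overlap. From each list they are up to 4 called members with the largest change, or up to 2 with the smallest p where none was called.

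The code was first tested on simulated data made from these values, with 200 changed genes. In polysomal RNA, darkness over light, 14.9% of genes changed by log2 0.5, 89.6% of those changed by 1 and 100% of those changed by 2 were called. For the change of the ratio these shares were 1.49%, 53.7% and 100%. A list shifted by log2 -0.3 was called, and 0 of the other lists were. The simulated values were drawn independently, without correlation between genes or a replicate effect. The test therefore cannot show how often lists are falsely called where genes vary together.

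Total and polysomal RNA with the same number come from 1 extract, and the numbers mark independent replicate experiments. In all 15 pairs of same-numbered arrays the deviations from the group means went together (r across probe sets 0.29 to 0.51, median 0.39), so the numbers pair the samples. A fit with the replicate as a block is given beside a result where it changes the call or moves a count by over 1.5 times. The other alternatives were an intensity trend, a mean of at least log2 5, a change of at least log2 1, other scalings, the arrays of 1 RNA pool alone, and leaving out each array in turn. Fits with an array left out and list tests with an estimated correlation were run without the block. A subtraction of carried-over RNA and the gene list tests with an array left out were added after the data were seen. With groups of 2, other splits of the arrays are too few to be informative, and within a group a stray array cannot be told from its partner.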

Results

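The series asked how a short darkness in the middle of the light period, and a short return of light, change the mRNAs of Arabidopsis seedlings and the share of them that is carried by ribosomes. The array data hold 2 replicates of total and 2 of polysomal RNA from each of 3 conditions: light, 1 h of darkness, and 1 h of darkness followed by 10 min of light (reillumination). Replicate arrays of a group correlated at r = 0.993 to 0.995 across probe sets. Arrays of the same RNA pool correlated at 0.983 to 0.997 for total and 0.979 to 0.992 for polysomal RNA, and arrays of different pools at 0.959 to 0.977. As a sign of RNA quality, the log2 ratio of the 3' to the 5' actin control probe set was 4.45 ± 0.20 (SD, n = 2) in light, 4.06 ± 0.40 in dark and 3.95 ± 0.32 in reilluminated total RNA. It was 3.75, 3.90 and 3.69 in the polysomal groups. The same ratio for GAPDH was 0.91, 1.11 and 1.01 in total and 1.13, 0.96 and 1.25 in polysomal RNA of light, darkness and reillumination, and for ubiquitin 1.56, 1.58 and 1.57, and 1.47, 1.32 and 1.39. The 2 actin probe sets are of different types by name, so their ratio is no clean measure of degradation. The gap between the pools varied with condition, and differently for the 3 controls. Whether RNA quality bears on changes of the polysomal-to-total ratio was not tested. The control probe set for 25S ribosomal RNA read log2 7.07 ± 1.06 (SD, n = 2), 7.47 ± 0.30 and 7.09 ± 0.59 in total RNA of the 3 conditions, so single arrays move these means, and 6.73 ± 0.13, 6.34 ± 0.16 and 6.35 ± 0.01 in polysomal RNA.

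**Figure D1:**
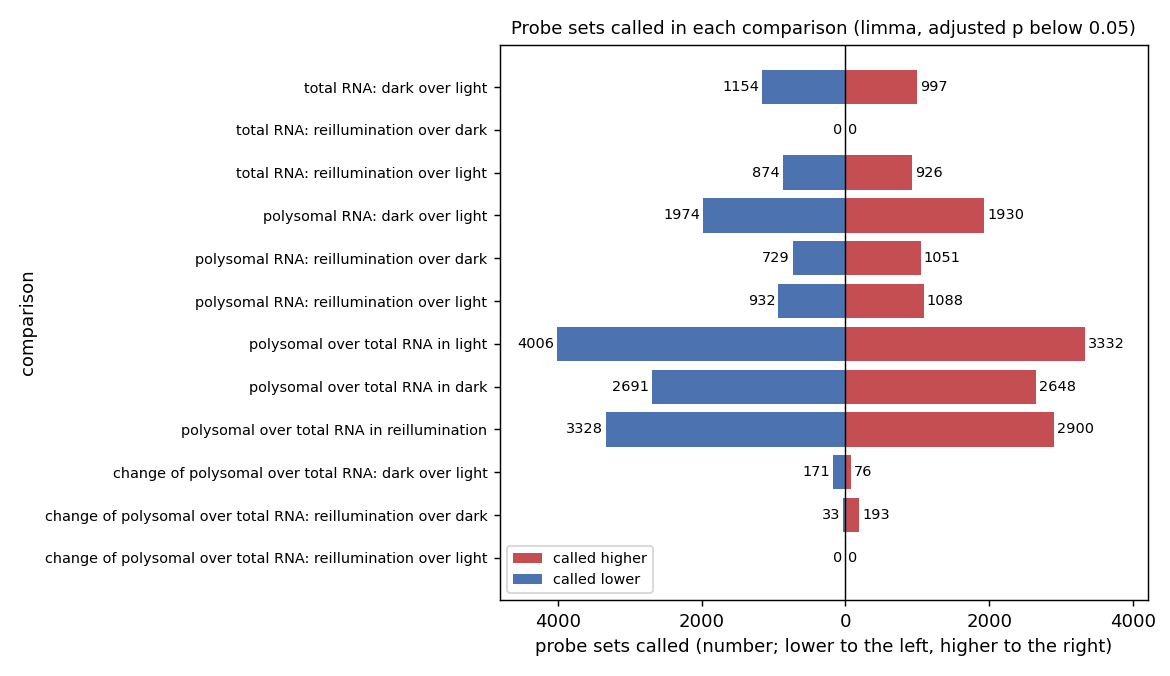
Number of probe sets called higher (red, to the right) and lower (blue, to the left) in each of the 12 comparisons, by limma at an adjusted p under 0.05. Reillumination over darkness has 0 calls in total RNA, and 1051 higher and 729 lower in polysomal RNA.

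The total RNA of seedlings held in darkness for 1 h, compared with light, shows which transcripts changed in amount. Genes known to respond to darkness and sugar starvation rose. PPDK, which encodes pyruvate orthophosphate dikinase, rose by log2 1.75 ± 0.12 (3.37-fold, adjusted p = 8.22e-06). ATL8, a RING-type ubiquitin ligase gene, rose by 1.52 ± 0.14. MCCA, for a subunit of methylcrotonyl-CoA carboxylase in leucine breakdown, rose by 1.64 ± 0.13 (adjusted p = 1.56e-05), and IVD, for isovaleryl-CoA dehydrogenase, by 1.43 ± 0.12. The largest rise was at AT1G15010, log2 3.29 ± 0.26 or 9.77-fold (adjusted p = 1.56e-05). The largest fall was at AT3G44450, log2 -3.17 ± 0.22 (adjusted p = 8.22e-06). AT1G72060, AT3G62950 and AT1G25400 rose by 2.98, 2.86 and 2.86, and AT5G01790 and AT4G16880 changed by -2.00 and -1.64.

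By list, all 6 measured dark and sugar-starvation genes were higher (median log2 1.48, camera adjusted p = 4.59e-14, and adjusted p = 0.0808 with an estimated correlation). Of 8 genes of branched-chain amino acid breakdown, 3 of which the former list also holds, 6 were higher (median 0.69, adjusted p = 2.34e-06, and 0.0869 as the adjusted p with an estimated correlation). In the elicitor and calcium list 6 of 17 genes were higher, and 9 when adjusted over the list alone (median 0.53, adjusted p = 4.9e-07, and adjusted p = 0.0929 with an estimated correlation). Among them were the calmodulin-like gene CML38 (2.77 ± 0.36), the transcription factor gene WRKY22 (2.27 ± 0.15) and the zinc finger gene STZ (1.70 ± 0.17). The chloroplast-encoded transcripts had a median of 0.19 with 1 of 69 called, and 0 when adjusted over the list alone (adjusted p = 0.000618, and adjusted p = 0.26 with an estimated correlation). Cytosolic ribosomal proteins (median -0.08, 2 of 129 lower, adjusted p = 0.0929) and light harvesting and photosystem genes (median -0.10, 0 of 6 called, adjusted p = 0.36) did not pass as lists. With the replicate as a block 10 elicitor genes and 2 chloroplast-encoded transcripts were higher, and 5 ribosomal protein genes and 1 light harvesting and photosystem gene lower. The clock gene GI fell by 0.65 ± 0.11 on the log2 scale (adjusted p = 0.00326). HYH, a relative of the light-signalling factor HY5, was at -0.65 ± 0.13 and called (adjusted p = 0.00708), but the call was lost without the light total array of replicate 2. HYH read log2 4.39 and 4.49 in light and 3.68 and 3.91 in darkness, where these arrays had lower quartiles of 4.07 to 4.13. The size of its fall may therefore be limited by the background.

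In limma, 997 probe sets were higher and 1154 lower in dark than in light total RNA (2151 of 22746), 327 and 101 of them by at least 2-fold. With the replicate as a block the counts were 1569 and 2024. Without the light total array of replicate 1 the total was 1379, without that of replicate 2 it was 983, and without the dark total array of replicate 2 it was 1040. For this comparison 29 of the 44 called genes named by the rule stayed called with each array left out.

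In the polysomal RNA the same comparison shows which transcripts changed in the ribosome capture. PPDK rose 4.61-fold (SE 0.12 on the log2 scale, adjusted p = 1.48e-06). MCCA rose by log2 2.13 ± 0.13 (adjusted p = 2.12e-06), ATL8 by 1.87 ± 0.14 and MCCB by 1.42 ± 0.10. CML38 rose by 3.00 ± 0.36, EXO, a gene of brassinosteroid-related growth, by 2.93 ± 0.23, and WRKY22 by 2.35 ± 0.15 (adjusted p = 4.04e-06). AT3G44450 had the largest fall, log2 -3.84 ± 0.22 (adjusted p = 1.55e-06). AT4G24700, AT1G20070 and AT3G52740 changed by -2.13, -2.04 and -2.03. The ribosomal protein transcripts called lower included AT1G74270 at -1.22 ± 0.18 (adjusted p = 0.000745), AT5G47700 at -0.98 ± 0.12 and AT4G39200 at -0.96 ± 0.12.

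Of 129 cytosolic ribosomal protein genes, 59 were lower and 0 higher, and 85 were lower when adjusted over the list alone. Their median was log2 -0.40, with 120 of 129 below 0 (adjusted p = 1.11e-18, and adjusted p = 0.217 with an estimated correlation). Of 69 chloroplast-encoded transcripts 32 were higher, and 37 when adjusted over the list alone (median 0.58, adjusted p = 1.48e-15). The transcripts psbT, psaA and psbB, for proteins of the photosystems, rose by 1.95 ± 0.27, 1.82 ± 0.24 and 1.65 ± 0.16. Chloroplast-encoded transcripts were strongly depleted from polysomal RNA in each condition, as given below, so these are changes of a small remainder in the capture. The 6 dark and sugar-starvation genes were all higher (median 1.68, adjusted p = 4.02e-12). Also higher were 5 of 8 genes of branched-chain amino acid breakdown, or 7 when adjusted over the list alone (median 0.81, adjusted p = 2.58e-07). The chloroplast, dark and branched-chain lists were called with an estimated correlation too, at an adjusted p of 0.0396, 0.0443 and 0.0443. In the elicitor and calcium list 9 of 17 were higher, and 10 when adjusted over the list alone (median 0.77, adjusted p = 1.2e-07, and adjusted p = 0.0633 with an estimated correlation).

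Smaller shifts passed in 4 more lists, and each call was lost with an estimated correlation. Nuclear-encoded thylakoid complex genes had a median of -0.22, with 4 of 21 lower and 7 when adjusted over the list alone (adjusted p = 0.00944, and adjusted p = 0.285 with an estimated correlation). TROL (-0.64 ± 0.12) and PSB27 (-0.57 ± 0.11) were among them. Plastid ribosomal protein genes had a median of -0.27, with 1 of 7 lower and 3 when adjusted over the list alone (adjusted p = 0.0114, and adjusted p = 0.361 with an estimated correlation). The called gene was AT5G65220 (-1.21 ± 0.15). Expansins and xyloglucan enzymes had a median of 0.11 with 7 of 28 higher and 1 lower (adjusted p = 0.0339, and adjusted p = 0.217 with an estimated correlation), led by EXLA1 at 2.03 ± 0.26, and with the replicate as a block 2 were lower. Autophagy genes had a median of 0.17 with 4 of 10 higher (adjusted p = 0.0454, and adjusted p = 0.379 with an estimated correlation), led by ATG8E (2.14-fold, SE 0.17 on the log2 scale). The block by replicate called 7 thylakoid complex and 3 plastid ribosomal protein genes lower. Without the dark polysomal array of replicate 1 these 4 adjusted p were 0.0666, 0.0608, 0.0738 and 0.211. The expansin list had an adjusted p of 0.0521 without the light polysomal array of replicate 1. Autophagy had one of 0.118 without that of replicate 2, 0.0837 with the replicate as a block and 0.0568 with the arrays centred on their medians.

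The other tested lists were not called in polysomal RNA after darkness. Light harvesting and photosystem genes had 1 of 6 lower (adjusted p = 0.187) and auxin-response genes 1 of 4 higher (adjusted p = 0.176). The mRNAs with conserved uORFs had 1 of 4 lower (adjusted p = 0.236) and core histones 0 of 6 called (adjusted p = 0.176). The auxin gene was WES1, which codes for an auxin-conjugating enzyme, at 1.70 ± 0.18. Chlorophyll and tetrapyrrole synthesis had 2 of 13 lower (adjusted p = 0.207): LIL3:2 at -0.93 ± 0.12, and CHLM, for a methyltransferase of chlorophyll synthesis, at -0.77 ± 0.12. Sugar transporters had 3 of 19 higher (adjusted p = 0.657) and the tricarboxylic acid cycle and respiration 1 of 12 higher (adjusted p = 0.497). Glutathione S-transferases had 1 of 14 higher and 1 lower (adjusted p = 0.657) and UDP-glucosyltransferases 6 of 47 higher and 5 lower (adjusted p = 0.298). Mitochondrion-encoded transcripts, tubulins and ribosome biogenesis had 0 of 11, 0 of 7 and 0 of 17 called, at adjusted p of 0.802, 0.899 and 0.473. With the replicate as a block more members of these lists were called: 2 auxin-response genes, 3 uORF mRNAs (1 higher, 2 lower), 5 sugar transporters (3 and 2), 2 of the tricarboxylic acid cycle, 17 UDP-glucosyltransferases (11 and 6), 3 glutathione S-transferases (2 and 1) and 3 genes of chlorophyll synthesis (1 and 2). It also called the mitochondrial nad1 (-0.44, adjusted p = 0.0365) and 3 ribosome biogenesis genes lower. Lists of fewer than 4 measured genes were not tested. Of these, 1 of 3 Calvin cycle genes was lower, and 0 of 3 PIF and shade-response genes and 0 of 2 root markers were called. STZ (1.90 ± 0.17), 1 of 3 rapid stress genes, was higher, 1 of 3 translation factor genes (AT5G19510, -0.74 ± 0.10) was lower, and 1 of 2 starch breakdown genes was higher. With the block 2 Calvin cycle genes were lower and 2 rapid stress genes higher. HYH fell by 0.85 ± 0.13 on the log2 scale, and GI was at 0.02 ± 0.11 (adjusted p = 0.938). In the dark polysomal arrays HYH read log2 4.16 and 4.38, again near their lower quartiles.

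In limma 1930 probe sets were higher and 1974 lower in dark than in light polysomal RNA (3904), 460 and 196 by at least 2-fold. The counts were 2585 without the dark array of replicate 1, 2311 without that of replicate 2, and 2124 without the light array of replicate 2. With each array left out 42 of the 60 called genes named by the rule stayed called. Total and polysomal RNA shared 742 probe sets called higher and 456 called lower, where independent lists would share 84.6 and 100.2. Another 10 and 8 were called in opposite directions. Total and polysomal RNA of a replicate come from 1 extract and deviated together, so part of the excess may come from shared deviations. With the replicate as a block 1904 calls were shared instead of 1198, and without the light total array of replicate 2 there were 731.

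**Figure D2:**
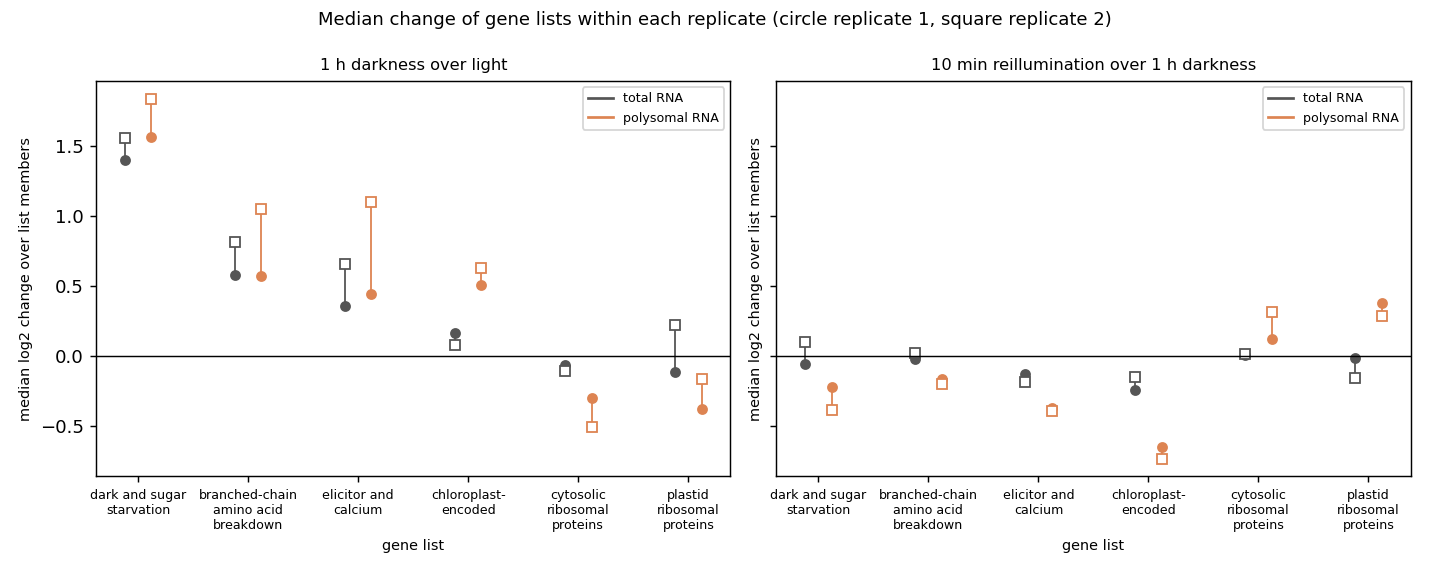
Median log2 change over the members of 6 gene lists within each replicate (circle replicate 1, square replicate 2) in total RNA (grey) and polysomal RNA (orange), for darkness over light on the left and reillumination over darkness on the right. The medians over both replicates in polysomal RNA were 0.58 and -0.64 for chloroplast-encoded transcripts and -0.40 and 0.19 for cytosolic ribosomal proteins.

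Reillumination for 10 min, compared with darkness, shows the early effect of returning light. In total RNA no probe set was called by limma (0 of 22746). In this fit, whose spread also holds the shared deviation of same-numbered arrays, 980 had an unadjusted p under 0.05 where 1137 are expected by chance. The smallest adjusted p was 0.178. With other settings 5 probe sets were called without the dark array of replicate 1 and 12 with the replicate as a block. WRKY22 was at -0.49 ± 0.15, GI at -0.02 ± 0.11 and psbA, for a core protein of photosystem II, at -0.45 ± 0.18, each with an adjusted p of 0.998. As lists, the chloroplast-encoded transcripts were lower (median -0.20, 0 of 69 called, adjusted p = 6.71e-09, and adjusted p = 0.148 with an estimated correlation). The elicitor and calcium list was lower too (median -0.07, 0 of 17 called, adjusted p = 0.0103, and adjusted p = 0.568 with an estimated correlation). Without the reilluminated array of replicate 1 the elicitor list had an adjusted p of 0.348, and 0.604 without the dark array of replicate 2. Its median turned to 0.01 without either of them, so its direction rests on single arrays.

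In polysomal RNA, reillumination changed many transcripts within 10 min. AT5G64180 rose by log2 1.73 ± 0.18 (3.32-fold, adjusted p = 0.000718), AT3G62190 by 1.55 ± 0.13 (adjusted p = 0.000575), AT3G14595 by 1.49 ± 0.14 and AT2G39000 by 1.41 ± 0.14. LIL3:2 and CHLM, which had fallen in darkness, rose by 0.87 ± 0.12 and 0.73 ± 0.12 (adjusted p = 0.00188 and 0.0053). Chloroplast-encoded transcripts, here too a small remainder in the capture, fell: psbT by 1.67 ± 0.27 on the log2 scale, psaA by 1.52 ± 0.24 and psbB by 1.34 ± 0.16 (adjusted p = 0.00495, 0.00412 and 0.00137). DIM1A, for an rRNA dimethylase of ribosome assembly, rose by 0.78 ± 0.12 (adjusted p = 0.00383). The clock gene GI was called lower, from log2 8.10 and 8.18 in the dark to 7.54 and 7.58 in the reilluminated polysomal arrays. It was also called lower than in light polysomal RNA, where it read 8.13 and 8.11.

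Of 69 chloroplast-encoded transcripts 30 were lower and 0 higher, and 45 were lower when adjusted over the list alone (median -0.64, adjusted p = 1.35e-21, and adjusted p = 0.0158 with an estimated correlation). Cytosolic ribosomal protein genes had a median of 0.19, with 18 of 129 higher, 27 when adjusted over the list alone, and 108 above 0 (adjusted p = 3.3e-09, and adjusted p = 0.521 with an estimated correlation). Plastid ribosomal protein genes had a median of 0.31, with 1 of 7 higher and 4 when adjusted over the list alone (adjusted p = 0.0017, and adjusted p = 0.521 with an estimated correlation). The elicitor and calcium list had a median of -0.28, with 3 of 17 lower and 5 when adjusted over the list alone (adjusted p = 0.000111, and adjusted p = 0.353 with an estimated correlation). The dark and sugar-starvation list had a median of -0.30, with 2 of 6 lower and 4 when adjusted over the list alone (adjusted p = 0.0152, and adjusted p = 0.521 with an estimated correlation). Its adjusted p was 0.0655 without the reilluminated polysomal array of replicate 2. In the fit with the block 30 cytosolic and 2 plastid ribosomal protein genes were higher and 6 elicitor genes lower. PPDK fell by 0.54 ± 0.12 on the log2 scale (adjusted p = 0.02) and ATL8 by 0.62 ± 0.14 (adjusted p = 0.0234). Both calls were lost without the dark array of replicate 2 (adjusted p = 0.149 and 0.0906) or the reilluminated array of replicate 2 (0.0944 and 0.161). PPDK was also not called without the reilluminated array of replicate 1 (0.086), nor ATL8 without the dark array of replicate 1 (0.12). With the replicate as a block, auxin-response (median -0.43, adjusted p = 0.157) and thylakoid complex genes (median 0.12, adjusted p = 0.068) were called too, at an adjusted p of 0.0267 and 0.0383. The thylakoid list had one of 0.0152 without the dark polysomal array of replicate 2.

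In limma 1051 probe sets were higher and 729 lower (1780), 94 and 22 of them by at least 2-fold. With the arrays centred on their medians, which moved the median of all probe sets by up to log2 0.11, the split was 1199 higher and 451 lower, and with the replicate as a block it was 1750 and 1680. The count was 749 without the dark array of replicate 1, 940 without the reilluminated array of replicate 1, 459 without the dark and 431 without the reilluminated array of replicate 2. Of the 34 called genes named by the rule 14 stayed called with each array left out.

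Whether reillumination turned back the changes of darkness was asked by matching the calls. In total RNA 0 probe sets were called in both comparisons in opposite directions by limma, since 0 were called on reillumination, where 980 had an unadjusted p under 0.05. There were 5 without the dark array of replicate 1 and 9 with the replicate as a block. In polysomal RNA 408 probe sets that rose in darkness fell on reillumination and 714 that fell in darkness rose, against 30 that moved in the same direction in both. Both comparisons use the dark arrays. Unchanged groups simulated on shared arrays gave 0 opposite calls, but few calls can arise where no group changes. Independent lists of these sizes would share 61.9 and 91.2. Part of the excess may come from the shared arrays. Changes of darkness in 1 replicate and of reillumination in the other share no array, and in a comparison chosen after the result was seen they correlated across probe sets at r = -0.42 and -0.44 in polysomal RNA, and at -0.10 and -0.14 in total RNA. The covariance of the changes across probe sets differed from the simulated one by -0.0539 in polysomal RNA and by -0.00677 in total RNA. The 1122 opposite calls became 2121 with the replicate as a block, and were split 238 and 813 with the arrays centred on their medians. There were 477, 639, 662, 307 and 315 without the dark array of replicate 1, the reilluminated array of replicate 1, the light, the dark and the reilluminated array of replicate 2, in that order.

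Reillumination over light shows what remained different from light after both steps, here in total RNA. MCCA and PPDK were higher by log2 1.73 ± 0.13 and 1.73 ± 0.12, IVD by 1.45 ± 0.12, and AKINBETA1, for a subunit of the SnRK1 kinase, by 1.45 ± 0.14. EXO and the cold-regulated gene COR27 were higher by 2.72 ± 0.23 and 2.36 ± 0.21, and AT3G44450 was at -3.08 ± 0.22. The dark and sugar-starvation list had 6 of 6 higher (median 1.45, adjusted p = 8.35e-15, and adjusted p = 0.0712 with an estimated correlation). For branched-chain breakdown it was 5 of 8 (median 0.67, adjusted p = 1.45e-05, and adjusted p = 0.111 with an estimated correlation), and for the elicitor list 4 of 17 (median 0.30, adjusted p = 0.000116, and adjusted p = 0.237 with an estimated correlation). Thylakoid complex genes had a median of -0.15 with 2 of 21 lower (adjusted p = 0.00592, and adjusted p = 0.393 with an estimated correlation). Cytosolic ribosomal proteins had one of -0.07 with 0 of 129 called (adjusted p = 0.0411, and adjusted p = 0.821 with an estimated correlation). Their adjusted p was 0.111 without the reilluminated array of replicate 1, 0.272 without the light array of replicate 2 and 0.0606 with the arrays centred on their medians. In limma 926 probe sets were higher and 874 lower (1800), 258 and 114 by at least 2-fold. Of those called after darkness 744 higher and 668 lower were called again (40.6 and 44.3 with independent lists). The comparisons share the light arrays, for which unchanged groups simulated, with few calls of any kind possible, gave 0 shared calls. The covariance exceeded the simulated one by 0.0848. The block by replicate called 3111, among them 7 elicitor genes higher, and 4 thylakoid complex and 5 cytosolic ribosomal protein genes lower. The count was 1133, 945, 837 and 852 without the light array of replicate 1, the reilluminated array of replicate 1, the light and the reilluminated array of replicate 2. With each array left out 30 of the 40 called genes named by the rule stayed called.

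In polysomal RNA, reillumination over light left EXO higher by log2 2.91 ± 0.23, AT4G33980 by 2.58 ± 0.17, COR27 by 2.44 ± 0.21, MCCA by 1.79 ± 0.13 and PPDK by 1.66 ± 0.12. AT3G44450 was at -3.69 ± 0.22 (adjusted p = 4.94e-06) and HYH at -1.09 ± 0.13 (adjusted p = 0.000266). In the reilluminated arrays HYH lay near the lower quartiles (log2 3.96 and 4.08). The dark and sugar-starvation list had 6 of 6 higher (median 2.64-fold, adjusted p = 1.52e-13, and adjusted p = 0.0654 with an estimated correlation). Branched-chain breakdown had 5 of 8 (median 0.73, adjusted p = 3.9e-07, and adjusted p = 0.0654 with an estimated correlation). The elicitor list had 4 of 17 (median 0.36, adjusted p = 0.00192, and adjusted p = 0.337 with an estimated correlation). Cytosolic ribosomal proteins had a median of -0.17 with 9 of 129 lower, 1 when adjusted over the list alone (adjusted p = 6.23e-08, and adjusted p = 0.59 with an estimated correlation). Expansins and xyloglucan enzymes had one of 0.17 with 5 of 28 higher and 2 lower (adjusted p = 0.018, and adjusted p = 0.273 with an estimated correlation). Their adjusted p was 0.0768 without the reilluminated array of replicate 1. In limma 1088 probe sets were higher and 932 lower (2020), 278 and 135 by at least 2-fold. Of those called after darkness 801 higher and 541 lower were called again, where independent lists would share 92.3 and 80.9. Unchanged groups simulated on the shared light arrays, with few calls of any kind possible, gave 0.05 shared calls. The covariance exceeded the simulated one by 0.0837. Part of the excess, here and in total RNA, may come from the shared light arrays. The block by replicate called 3409, among them 8 elicitor genes higher and 19 cytosolic ribosomal protein genes lower. The count was 1133, 1242, 988 and 1054 without the light array of replicate 1, the reilluminated array of replicate 1, the light and the reilluminated array of replicate 2. With each array left out 25 of the 48 called genes named by the rule stayed called.

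**Figure D3:**
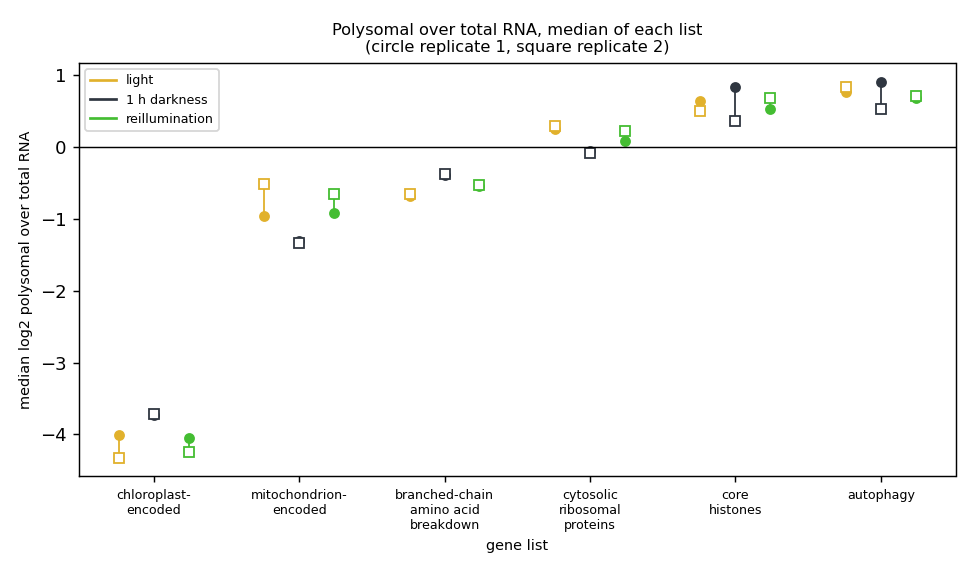
Median log2 polysomal over total RNA of 6 gene lists within each replicate (circle replicate 1, square replicate 2), in light (yellow), darkness (black) and reillumination (green). Chloroplast-encoded transcripts lie lowest, at -4.16 in light, -3.66 in darkness and -4.20 in reillumination over both replicates.

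Polysomal over total RNA within a condition shows which transcripts were carried by tagged ribosomes more or less than others. Transcripts encoded in the organelles, which are translated on ribosomes of their own without the tagged protein, were depleted, and the chloroplast-encoded ones had the lowest median of the 21 lists in each condition. In light rpl22 was at log2 -6.01 ± 0.14 (64.3-fold, adjusted p = 9.32e-10), psaA at -5.65 ± 0.24 and the mitochondrial nad4 at -2.23 ± 0.18. All 69 chloroplast-encoded transcripts were lower in each of the 3 conditions (medians -4.16, -3.66 and -4.20 in light, darkness and reillumination, adjusted p = 1.46e-67, 7.06e-82 and 7.75e-79). Also lower were 8 of 11 mitochondrion-encoded ones (medians -0.73, -1.20 and -0.78, adjusted p = 7.8e-05, 1.12e-06 and 6.05e-06). The mitochondrial list had medians of log2 3.95 to 4.16 in the polysomal arrays, near their lower quartiles of 4.09 to 4.17. The size of its depletion, and differences in it between conditions, may therefore be limited by the background. With an estimated correlation the adjusted p were 0.000631, 0.000359 and 0.000401 for the chloroplast and 0.0363, 0.0148 and 0.0217 for the mitochondrial list.

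Of 10 autophagy genes 8 were higher in each condition (medians 0.77, 0.68 and 0.69, adjusted p = 7.8e-05, 2.37e-06 and 6.05e-06, and adjusted p = 0.206, 0.128 and 0.189 with an estimated correlation). ATG8D and ATG8G, for proteins of the autophagosome membrane, were at 1.26 ± 0.14 and 1.02 ± 0.12 in light. Core histone genes were higher for 4, 4 and 5 of 6 (medians 0.58, 0.67 and 0.58, adjusted p = 0.0127, 0.0139 and 0.013, and adjusted p = 0.262, 0.283 and 0.248 with an estimated correlation), with HTB2 at 0.93 ± 0.16 in light. Genes of branched-chain breakdown were lower for 7, 4 and 5 of 8 and higher for 1 (medians -0.72, -0.38 and -0.56, adjusted p = 0.00492, 0.0299 and 0.013, and adjusted p = 0.206, 0.291 and 0.248 with an estimated correlation). Chlorophyll and tetrapyrrole synthesis was lower for 6, 4 and 4 of 13 (medians -0.42, -0.29 and -0.32, adjusted p = 0.0259, 0.0139 and 0.024, and adjusted p = 0.206, 0.128 and 0.198 with an estimated correlation). The elicitor list was higher for 5, 9 and 5 of 17 (medians 0.44, 0.63 and 0.37, adjusted p = 0.0137, 4.97e-05 and 0.024, and adjusted p = 0.319, 0.128 and 0.414 with an estimated correlation). The block by replicate gave 9 elicitor genes higher and 1 lower in light, 10 and 1 in reillumination, and for chlorophyll synthesis 1 higher and 5 lower in darkness and 7 lower in reillumination. Of 2 root markers, EXPA7 was at -1.11 ± 0.19 and PYK10 at -0.37 ± 0.12 in light, and both starch breakdown genes measured, PWD and DPE1, were at -1.24 ± 0.10 and -0.88 ± 0.11. Some list calls were lost with 1 array left out, at these adjusted p. In darkness it was the branched-chain list without the polysomal array of replicate 1 (0.0845) or the total array of replicate 2 (0.0721). In light it was chlorophyll synthesis without the total array of replicate 2 (0.0669). In reillumination it was chlorophyll synthesis without the polysomal array of replicate 2 (0.0566) and the elicitor list without the total array of replicate 1 (0.0727).

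Cytosolic ribosomal proteins went both ways. In light 48 of 129 were higher and 13 lower, 54 and 14 when adjusted over the list alone (median 0.27, adjusted p = 9.18e-05, and adjusted p = 0.547 with an estimated correlation), with AT2G32220 at 1.45 ± 0.16 and AT2G40010 at -1.52 ± 0.12. In darkness 17 were higher and 28 lower (median -0.05, adjusted p = 0.201), and in reillumination 35 were higher and 15 lower (median 0.14, adjusted p = 0.024, and adjusted p = 0.686 with an estimated correlation). The call in reillumination was lost without the polysomal array of replicate 2 (adjusted p = 0.333) and with all arrays quantile normalized again (0.144).

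In limma 3332 probe sets were higher and 4006 lower in polysomal than in total RNA of light (7338), 2648 and 2691 in darkness (5339), and 2900 and 3328 in reillumination (6228). Centring the arrays on their medians turned these splits to 4677 and 3000 in light, 3031 and 2317 in darkness, and 4124 and 2446 in reillumination. The total was 3367 in darkness without the polysomal array of replicate 1 and 3971 in reillumination without the total array of replicate 1. Of the called genes named by the rule, 56 of 88, 56 of 78 and 54 of 78 stayed called with each array left out.

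The change of the polysomal-to-total ratio between conditions tests whether ribosome-carried RNA changed otherwise than total RNA. From light to darkness the ratio rose for the chloroplast transcripts psaA (log2 1.76 ± 0.34, adjusted p = 0.0395), ycf4 (1.37 ± 0.18, adjusted p = 0.0186) and psbB (1.36 ± 0.23, adjusted p = 0.0334). It also rose for PWD, for a starch-phosphorylating enzyme (0.65 ± 0.14, adjusted p = 0.0485). It fell at AT5G03050 (-2.04 ± 0.27, adjusted p = 0.0186) and CHLM (-0.92 ± 0.17, adjusted p = 0.0359). Among ribosomal protein genes it fell at AT1G74270 (-1.35 ± 0.25, adjusted p = 0.0374) AT5G47700 (-1.06 ± 0.17, adjusted p = 0.0323), and the plastid ribosomal protein gene AT5G65220 (-1.35 ± 0.22, adjusted p = 0.0309). From darkness to reillumination it rose at AT3G62190 (1.85 ± 0.19, adjusted p = 0.0059), LIL3:2 (0.99 ± 0.16), CHLM (0.93 ± 0.17) and AT5G47700 (0.91 ± 0.17), and fell at psbB (-1.19 ± 0.23) and ycf4 (-0.96 ± 0.18). The ratio of GI was not called in darkness (0.67 ± 0.16, adjusted p = 0.06), but was with the replicate as a block (adjusted p = 0.0211).

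By list, the ratio of cytosolic ribosomal proteins had a median change of -0.29 in darkness, with 111 of 129 below 0, 4 lower, and 12 when adjusted over the list alone (adjusted p = 1.37e-14, and adjusted p = 0.436 with an estimated correlation). On reillumination it was 0.22, with 100 above 0 and 1 higher (adjusted p = 4.35e-08, and adjusted p = 0.546 with an estimated correlation). Chloroplast-encoded transcripts had a median change of 0.42 in darkness, with 8 of 69 higher and 23 when adjusted over the list alone (adjusted p = 2.02e-08, and adjusted p = 0.182 with an estimated correlation). On reillumination it was -0.47, with 2 lower and 11 when adjusted over the list alone (adjusted p = 2.48e-10, and adjusted p = 0.104 with an estimated correlation). Plastid ribosomal proteins were at -0.24 in darkness (1 of 7 lower, adjusted p = 0.00788, adjusted p = 0.436 with an estimated correlation, and 0.0501 without the dark total array of replicate 2) and at 0.36 on reillumination (0 of 7 called, 2 when adjusted over the list alone, adjusted p = 0.000819, and adjusted p = 0.546 with an estimated correlation). With the replicate as a block 23 cytosolic ribosomal protein genes were lower and 22 chloroplast-encoded transcripts higher in darkness, and on reillumination 11 of the former were higher and 10 of the latter lower. It also called 2 plastid ribosomal protein genes higher on reillumination, among them AT5G65220 (0.97, adjusted p = 0.0041). On reillumination the dark and sugar-starvation list was at -0.38 (adjusted p = 0.014) and the thylakoid complexes at 0.20 (adjusted p = 0.0131), both with an adjusted p = 0.546 with an estimated correlation. The former was not called without the reilluminated total (0.0896) or polysomal (0.0606) array of replicate 2, nor the latter without the dark polysomal array of replicate 1 (0.122) or the dark total array of replicate 2 (0.0718).

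In limma the ratio was higher for 76 probe sets and lower for 171 in darkness (247), and higher for 193 and lower for 33 on reillumination (226). These counts depended on single arrays in the fit without the replicate as a block, and the fit with the block was not repeated with an array left out. For darkness they were 5 and 0 without the light total arrays of replicates 1 and 2, 537 and 0 without the dark total arrays, 0 and 0 without the light polysomal and 0 and 1 without the dark polysomal arrays. For reillumination, in the same order of replicates, they were 357 and 4 without the dark total, 2 and 4 without the reilluminated total, 5 and 4 without the dark polysomal, and 26 and 5 without the reilluminated polysomal arrays. Of the called genes named by the rule, 0 of 20 stayed called with each array left out in darkness and 1 of 16, AT3G62190, on reillumination. The block by replicate gave 1712 (860 higher, 852 lower) and 1086 (716 and 370), and centring on the medians split the dark count into 39 higher and 212 lower and that of reillumination into 250 and 15. Of the 171 probe sets lower in darkness 110 were higher on reillumination, and of the 76 higher 13 were lower, where independent lists would share 1.45 and 0.110. The simulated shared dark arrays gave 0.05 such calls in all, but few calls can arise where no group changes. The covariance lay below the simulated one (difference -0.0597), and part of the excess may come from the shared dark arrays.

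From light to reillumination the ratio was called for 0 of 22746 probe sets by limma, with 621 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00, and 0 with the replicate as a block. As a list, cytosolic ribosomal proteins had a median change of -0.11 (adjusted p = 2.3e-05, and adjusted p = 0.772 with an estimated correlation), which was not called without the reilluminated polysomal array of replicate 1 (0.48) or the light polysomal array of replicate 2 (0.666). The mRNAs with conserved uORFs were at -0.28 (adjusted p = 0.0564, and 0.0218 with the replicate as a block).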

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

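Of the tests in this part, the subtraction of carried-over RNA as an alternative fit, the tests of a general narrowing and the test of noise were chosen only after the result was seen. The bound of the narrowing test on ribosomal proteins was also changed after its values were seen, and under the earlier bound, a median of at most -0.2 left in both replicates, that test was undecided. The results listed here drew attention because the change of polysomal RNA differed from that of total RNA by an interaction test in limma or, for lists, in camera. The contrast of calls on reillumination between the pools, treated last, compares separate counts instead.

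From light to darkness 247 probe sets differed in this way, and from darkness to reillumination 226. In darkness the ratio of polysomal to total RNA changed by a median of log2 0.42 for chloroplast-encoded transcripts, -0.29 for cytosolic ribosomal proteins and -0.24 for plastid ribosomal proteins, all 3 calls lost with an estimated correlation (adjusted p = 0.182, 0.436 and 0.436). On reillumination it changed by -0.47, 0.22 and 0.36 for the same lists, by -0.38 for dark and sugar-starvation genes and by 0.20 for nuclear-encoded thylakoid complexes. These 5 calls too were lost with an estimated correlation (adjusted p = 0.104, then 0.546 for each of the other lists). From light to reillumination the cytosolic ribosomal proteins had a median change of -0.11, and the call was lost with an estimated correlation (adjusted p = 0.772), without the reilluminated polysomal array of replicate 1 (0.48) and without the light polysomal array of replicate 2 (0.666). Single arrays also ended the calls of the plastid list in darkness (0.0501 without the dark total array of replicate 2) and, on reillumination, of the dark and sugar-starvation list (0.0896 and 0.0606 without the reilluminated total or polysomal array of replicate 2) and the thylakoid list (0.122 without the dark polysomal array of replicate 1, 0.0718 without the dark total array of replicate 2).

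Among single genes the ratio rose in darkness for psaA (1.76), AT3G56080 (1.49), ycf4 (1.37), psbB (1.36), rpl22 (1.26), AT5G52280 (1.25) and PWD (0.65). It fell for AT5G03050 (-2.04), AT5G50335 (-1.46), AT4G16447 (-1.45), AT5G64180 (-1.43), AT1G28150 (-1.41), AT1G49170 (-1.36), CHLM (-0.92) and the translation factor gene AT5G19510 (-0.71). It also fell for the ribosomal protein genes AT1G74270 (-1.35), AT5G47700 (-1.06), AT5G48760 (-0.87) and AT2G27720 (-0.78), and for the plastid one AT5G65220 (-1.35). On reillumination it rose for AT3G62190 (1.85), AT5G52960 (1.73), AT3G14595 (1.70), AT5G64180 (1.62), AT2G39000 (1.47), AT1G70900 (1.43), LIL3:2 (0.99), CHLM (0.93), AT5G47700 (0.91) and AT5G19510 (0.70). It fell for psbB (-1.19), AT4G01290 (-1.12), AT1G30600 (-0.99), ycf4 (-0.96), AT1G72500 (-0.92) and TRM15 (-0.87). With each array left out, 0 of the 20 genes called in darkness and 1 of the 16 called on reillumination, AT3G62190, stayed called.

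The ratio of cytosolic ribosomal protein mRNAs fell in darkness by a median of 0.26 in replicate 1 and 0.36 in replicate 2 on the log2 scale, with 104 and 113 of 129 below 0. Carry-over of unbound RNA into the dark captures was not decided by subtracting it, which left medians of -0.27 and -0.38. Subtraction moves ratios away from log2 0. The list had medians of 0.26 and 0.29 in light and -0.05 and -0.08 in darkness, so subtraction could hardly make the fall smaller. Normalization that depends on intensity is argued against: the lowest median among 10000 lists matched on mean level was -0.13. A general narrowing of polysomal over total RNA differences in the dark arrays is argued against as the whole cause, since medians of -0.17 (95% bootstrap interval -0.22 to -0.09) and -0.34 (-0.41 to -0.27) remained after its predicted part of -0.08 and -0.06 was taken off, and members below the centre of the narrowing, predicted to rise, had medians of -0.11 (interval -0.22 to 0.01) and -0.30 (-0.42 to -0.19), with intervals over genes that are not independent. Lower ribosome loading of these mRNAs in darkness may be behind part of the fall, as a hypothesis found and tested on the same data, while parts by carry-over or narrowing stay open.

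Chloroplast-encoded transcripts rose in the ratio in darkness by a median of 0.38 and 0.59 in the replicates, with 50 and 53 of 69 above 0, while mitochondrion-encoded ones were at -0.22 and -0.21. The mitochondrial list lay near the background in polysomal RNA (medians log2 3.98 and 4.02 in darkness), so it is a weak comparison. Normalization that depends on intensity was not decided, although the highest median among 10000 lists matched on mean level was 0.28. In light replicate 1 the chloroplast-encoded transcripts had a median of log2 10.66 in total and 6.24 in polysomal RNA. Lists matched on the mean over all arrays need not have either level. Carry-over of unbound RNA stays open. Nuclear transcripts depleted from polysomal RNA rose by a median of 0.30 and 0.29 over 65 and 63 probe sets chosen in the other replicate. Carry-over would raise them, but so would a narrowing, with nuclear slopes of -0.20 and -0.30, so the rise does not tell the 2 apart. The carried-over share, 7.55% and 7.60% in darkness and 6.22% and 4.99% in light, predicts a rise of only 0.06 and 0.12. This share was computed from the chloroplast transcripts themselves, and so is no separate measure of carry-over. The line for a general narrowing was fitted on nuclear probe sets, whose ratios had an SD of 0.47 in both light replicates. It was extended to chloroplast medians of -4.01 and -4.32 in light. The change from light to reillumination was at most 0.135 times the predicted 0.41 and 0.42, and in darkness the slope predicted at least 2.08 times the observed change. So far from most fitted values the line cannot decide on a narrowing that acts alike in darkness and reillumination. A narrowing of the dark arrays alone, which the steeper slope in darkness would allow, may still account for part of the rise. By spread, however, darkness hardly stood apart from reillumination. The covariance of nuclear ratios between replicates was 0.140 in darkness, 0.149 in reillumination and 0.186 in light. A change of the chloroplast transcripts themselves in darkness was not separated from carry-over or narrowing.

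On reillumination 1780 probe sets were called in polysomal RNA and 0 in total RNA, where 980 had an unadjusted p under 0.05 in limma. The interaction test, which compares the pools directly, called 226. Larger noise in the total RNA arrays is argued against, because the covariance of the changes between replicates in total RNA was 0.133 times that in polysomal RNA, while the root mean square difference between replicates was 1.00 times as large. Carry-over was not decided: with the carried-over share subtracted 2122 probe sets were called, 1232 higher and 890 lower. A share of at most 7.60% changes most ratios little, so the count could hardly fall. The share also came from the chloroplast transcripts and is no separate measure of carry-over. A fast change of the mRNAs on ribosomes that runs ahead of their total amount may be behind the pattern, as a hypothesis found and tested on the same data, while carry-over stays open. A change of both pools too small for 2 arrays in total RNA stays open.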

How the results depend on the processing

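The subtraction of carried-over RNA and the gene list tests with an array left out were chosen only after the data were seen. Among called values for named genes, 0 changed sign in the alternatives run on them, which leave out the subtraction of carried-over RNA. Lists were run with an estimated correlation, median centring, quantile normalization, the replicate as a block and each array left out. Among called lists 0 reversed direction by camera, but the median of the elicitor list in total RNA, reillumination over darkness, changed sign in 2 fits with an array left out (0.01 against -0.07). Of 817 values for named genes, 807 stayed on their side of the threshold with an intensity trend, 767 with arrays centred on their medians, 799 with all arrays quantile normalized again and 802 with this done within each pool. With only the arrays of 1 pool in the fit 345 of 378 did, and with a mean of at least log2 5 it was 753 of 757. Of 252 list tests, 250 stayed with median centring, 247 with quantile normalization and 197 with an estimated correlation, where 10 were called instead of 65, 3 up and 7 down. Quantile normalization over all arrays called the cytosolic ribosomal proteins in dark over light total RNA (adjusted p = 0.0259, median log2 -0.09, and below 0 in both replicates without it), and no longer called ribosome biogenesis in polysomal over total RNA of light (0.103). It also called the dark and sugar-starvation list in reilluminated polysomal over total RNA (0.0494) and the uORF list in the change of the ratio from light to reillumination (0.0449). The cause was not tested. The replicate as a block raised the calls to 3593 (total RNA, darkness over light), 12 (reillumination over darkness) and 3111 (reillumination over light), and in polysomal RNA to 3430 (reillumination over darkness) and 3409 (reillumination over light). For the change of the ratio the block gave 1712 in darkness and 1086 on reillumination, and a block by extract 1734 and 1002. Calls reversed on reillumination became 9 in total and 2121 in polysomal RNA, and shared dark calls 1904. The block takes up the shared deviation of same-numbered arrays by construction. It added 55 calls and ended 0 among the 817 values for named genes, changed the calls of the 4 lists given beside their results, and changed no other call of these. A change of at least log2 1 in addition left 428 and 372 calls in total RNA (darkness and reillumination over light), and 656, 116 and 413 in polysomal RNA (darkness over light, reillumination over darkness, reillumination over light). It left 1226, 753 and 803 in polysomal over total RNA of light, darkness and reillumination, 98 and 102 in the changes of the ratio, 48 reversed and 322 shared calls, fewer by construction. A mean of at least log2 5, with fewer probe sets tested, gave 420 calls for the ratio in darkness. Subtracting carried-over RNA, with 140 probe sets at the floor left out, gave 553 calls for the ratio in darkness and 383 on reillumination, and the cause was not tested. Leaving out each array in turn, which leaves 1 array in a group and assumes that it varies like the others, gave 983 to 2065 calls for darkness over light, 0 to 5 for reillumination over darkness and 837 to 1133 for reillumination over light in total RNA. In polysomal RNA it gave 2124 to 2760, 431 to 940 and 988 to 1242. Polysomal over total RNA had 5200 to 5590 calls in light, 3367 to 4156 in darkness and 3971 to 4737 in reillumination. The changes of the ratio had 0 to 537 in darkness, 2 to 357 on reillumination and 0 to 0 from light to reillumination, where 621 had an unadjusted p under 0.05 in limma. Reversed calls ranged from 0 to 5 in total and 307 to 828 in polysomal RNA, shared calls from 731 to 1055, and called lists from 59 to 68. Of 3980 values for named genes 3276 kept their side, 692 lost and 12 gained a call, and of 1260 list tests 1212 kept theirs, 28 lost and 20 gained. Fewer arrays make changes harder to call by construction, but some calls were gained with an array left out. What limits precision is the number of arrays, and dim probe sets lie near the background.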

Other observations

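The spread of the polysomal-to-total ratio and the crossed replicates below were computed only after the results were seen. Beyond the groups described so far, CYTC-1 and CYTC-2, genes of cytochrome c, the electron carrier of the respiratory chain, were higher in polysomal than in total RNA. CYTC-2 was at log2 1.37 ± 0.14 in light, 1.27 ± 0.14 in darkness and 1.08 ± 0.14 in reillumination, called in each with each array left out, and CYTC-1 was at 0.75 ± 0.13 in light. In the same list SDH1-1, for a subunit of succinate dehydrogenase, was at -1.21 ± 0.23 in reillumination, and cICDH, for a cytosolic isocitrate dehydrogenase, at -0.59 ± 0.11 in light. Of 12 measured genes of the tricarboxylic acid cycle and respiration 2 were higher and 4 lower in light. Of 14 glutathione S-transferase genes 2 were higher and 2 lower, with GSTU28 at -0.91 ± 0.13, and of 7 tubulin genes TUA6 was lower at -0.85 ± 0.14. All 3 measured Calvin cycle genes were lower in polysomal than in total RNA of darkness and of reillumination, and 2 of 3 in light, with SBPASE at -0.78 ± 0.12.

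More genes of ribosome biogenesis were called lower than higher in polysomal over total RNA: 8 of 17 were lower and 3 higher in light, 8 and 0 in darkness (10 and 2 with the replicate as a block), and 7 and 2 in reillumination. PRH75, an RNA helicase gene, was at -1.24 ± 0.17, -0.97 ± 0.17 and -1.11 ± 0.17, and NRPA2, for a subunit of RNA polymerase I, at -1.13 ± 0.12 in light and -1.05 ± 0.12 in reillumination. The list had medians of -0.47, -0.41 and -0.30, below 0 in both replicates of each condition, with adjusted p of 0.0466, 0.00412 and 0.0249 in camera. These calls were lost with an estimated correlation (adjusted p = 0.532, 0.291 and 0.517). In light it was lost without the polysomal array of replicate 1 (0.0894), without the total array of replicate 2 (0.0813) and with all arrays quantile normalized again (0.103), and in reillumination without the polysomal array of replicate 1 (0.165).

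UDP-glucosyltransferase genes went both ways after darkness. In total RNA UGT78D1 and UGT76E11 were at -1.31 ± 0.16 and -1.08 ± 0.15 and UGT85A5 at 0.80 ± 0.11, with 2 of 47 higher and 4 lower, or 2 and 8 with the replicate as a block.

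Over 13367 nuclear probe sets the SD of the polysomal-to-total log2 ratio was 0.47 and 0.47 in the light replicates, 0.44 and 0.41 in darkness, and 0.42 and 0.42 in reillumination. The change of this ratio from light to darkness had a slope of -0.30 and -0.20 on the ratio in light, taken from the other replicate. From light to reillumination the slope was -0.10 and -0.10. The covariance of the ratio between replicates was 0.186 in light, 0.140 in darkness and 0.149 in reillumination.

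Changes of darkness over light in 1 replicate, set against changes of reillumination over darkness in the other, share no array. Across probe sets, which are not independent replicates, they correlated at r = -0.42 and -0.44 in polysomal RNA and at -0.10 and -0.14 in total RNA.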
